A study of Mus musculus with 64 samples.

How the data were processed

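Spike-in ChIP-seq was carried out on mESCs of 4 lines with and without 4OHT, per the labels' protocols. Mouse and fly S2 cells were fixed with 25 mM DSG for 40 min and 1% formaldehyde for 15 min, and their extracts were mixed at 9 parts of mouse to 1 part of fly DNA. H3K9me2 was immunoprecipitated with 1 µg of the antibody ab1220, with no separate antibody for the fly chromatin. Lamin B1 was immunoprecipitated with 1 µg of its antibody together with 0.5 µg of an antibody against H2Av, a fly histone variant, so its ratio has no absolute meaning and is compared between genotypes only. Libraries were sequenced with paired reads of 150 nt.

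The deposited table holds whole-number read counts per library and genome, which the authors obtained with Bowtie2, SAMtools and deepTools 3.5.2 on builds mm10 and dm6, per the submitters' processing notes. Those notes name fastp 0.23.4, a read trimmer, for all 16 samples of line SE and all 16 of 3S1G, and for 0 of 16 of 33-6 and 0 of 16 of SG. Mapping filters and duplicate removal are not given in the sources used here. All 160 counts are even, so both mates of a pair appear to have been counted, and counting intervals were computed on pairs. The deposited table also holds a mouse to fly ratio per ChIP and input library and a scaling factor, per the file headers. The deposited scaling factor is itself a ratio, and it equalled the ChIP ratio divided by the input ratio in 40 of 40 libraries, to a relative tolerance of 1e-09. The table has 1 entry for each of the 24 H3K9me2 and 16 Lamin B1 libraries with its input, which covers all 64 samples. It writes the SE and 3S1G lines with a suffix, and these entries were matched by the line name, treatment and lot. No 2 libraries had identical counts. Tracks along the genome were not analysed here.

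From the counts, the normalised ratio was computed as mouse over fly reads in the ChIP library, divided by the same quantity in the input of the same line, treatment and lot. Differences were taken between log2 values. Each antibody had 7 contrasts. The effects of losing Setdb1, G9a and Suv39h1/2 were each averaged over 4 pairs of genotypes and tested by exact two-sided permutation of labels within strata, with 160000 assignments for H3K9me2 and for inputs and 1296 for Lamin B1. The 4 interactions were tested by permuting residuals of the model without the term (Freedman-Lane), with 100000 resamples. An interaction is the difference between the effects of one loss without and with the other. P-values were adjusted by Benjamini-Hochberg over the 7 contrasts of an antibody, with a threshold of 0.05, and over 3 for the inputs. Intervals of 95% used the SD pooled over the 8 genotypes. Single genotypes were compared by exact permutation tests, and correlations by exact permutation of pairings. Comparisons and alternatives were fixed before the data were examined, except where stated. No gene was to be named as measured unless the table held genes, and it held none. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

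The tests were run on simulated normal values with the pooled SD of each antibody, in 200 simulations each. These values had the same spread in every genotype and no lot shift. The H3K9me2 libraries differ from that: their log2 SD ran from 0.51 to 1.85 over genotypes, and their lots differed. Calls were counted without adjustment over the 7 contrasts, so the rates below hold for that simpler setting only. With no effect planted, the test of an effect made calls at 0.05 in 3.00% of simulations for the 24 H3K9me2 libraries and 6.00% for the 16 Lamin B1 libraries. The plain interaction contrast planned at first made calls in 12.5% and 15.5%, so it was replaced after the results had been seen by its t statistic from a refit to the permuted residuals, which made calls in 7.00% and 4.00%. The enumeration of splits planned for Lamin B1 was replaced by 100000 resamples in the same step, and was not itself simulated. A planted log2 effect of 2 was found in 100% of H3K9me2 simulations and an interaction of that size in 65.0%. A planted log2 effect of 0.5 was found in 83.5% of Lamin B1 simulations and an interaction of that size in 29.5%.

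The lot number is shared by samples of all genotypes, and what it is a lot of is not given in the sources used here. It was taken as a shared batch: H3K9me2 libraries of lot 7 were the lowest in 8 of 8 genotypes, and an exact permutation test over the orders of the lots gave p = 3.93e-05. The Lamin B1 libraries showed no common shift between lots 1 and 4 (p = 0.781 by the same exact permutation test). They hold no lot 7, so they cannot show whether its shift is shared. The main contrasts carry no block, and fits with lot as a block were an alternative. Other alternatives were no input correction, an input ratio averaged over lots, the deposited scaling factor, the linear scale, medians over lots, leaving out each lot or library, lots 1 and 4 only, and each set of lines alone.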

Results

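Chromatin of mouse embryonic stem cells (mESCs, strain TT2) was profiled by spike-in ChIP-seq for H3K9me2, the dimethylated form of histone H3 lysine 9, and for Lamin B1, a structural protein of the nuclear lamina. Lysine 9 of H3 is methylated by several enzymes, and the series removed 3 activities in combination: Setdb1, G9a and the pair Suv39h1 and Suv39h2 (written Suv39h1/2). There were 4 cell lines, namely 33-6, in which Setdb1 can be deleted by 4-hydroxytamoxifen (4OHT), a G9a-knockout line (SG), a Suv39h1/2 double-knockout line (SE) and a line that lacks G9a and Suv39h1/2 (3S1G). Each line was profiled without 4OHT and after 96 h in 800 nM 4OHT, which deletes Setdb1. This gave 8 genotypes: control, Setdb1-KO, G9a-KO, G9a;Setdb1-DKO, Suv39h1/2-DKO, Suv39h1/2;Setdb1-TKO, G9a;Suv39h1/2-TKO and G9a;Suv39h1/2;Setdb1-QKO. Each genotype had 3 H3K9me2 libraries and 3 input libraries, from lots numbered 1, 4 and 7, and 2 Lamin B1 libraries, from lots 1 and 4. That makes 24 H3K9me2, 24 input and 16 Lamin B1 libraries.

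Chromatin of Drosophila S2 cells, a fly cell line, was added to the mouse chromatin before immunoprecipitation, so that the fly reads serve as a constant against which the total mouse signal is read. The value reported is the mouse to fly read ratio of the ChIP library divided by that of its input library, called the normalised ratio below. It describes the whole genome at once, so no gene or region is resolved in these data. The H3K9me2 libraries held 20.5 M to 84.4 M mapped reads, the Lamin B1 libraries 37.7 M to 186 M reads and the input libraries 30.6 M to 131 M reads. At this depth the 95% counting interval of a normalised ratio was at most ±0.219% of its value for H3K9me2 and at most ±0.219% for Lamin B1. These intervals cover counting error only and take each read pair as independent. The spread between libraries was far wider. With 1 line per genotype, and nothing in the labels that describes separate cultures, p-values measure the spread between these libraries.

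The first question was how much H3K9me2 remains when G9a, which dimethylates H3K9, is lost. H3K9me2 was much lower in every G9a-deficient genotype. In control cells the normalised ratio was 0.979 ± 0.368 (SD, n = 3), and in G9a-KO cells it was 0.219 ± 0.113 (SD, n = 3). The geometric mean of G9a-KO cells was 21.9% of the control, and that of G9a;Setdb1-DKO cells was 19.2%. Background mouse reads were not measured, so these percentages include any such background. In the untreated lines that also lacked Suv39h1/2, the ratio was 0.610 ± 0.198 (SD, n = 3) with G9a and 0.0681 ± 0.0443 (SD, n = 3) without it. Over all 4 pairs of genotypes that differ in G9a status, H3K9me2 was 7.72-fold lower without G9a. This is a log2 difference of −2.95 with a 95% interval of −3.79 to −2.11. Each pair also sets different lines side by side, so G9a loss cannot be separated from other differences between lines. The exact two-sided permutation test within strata gave p = 1.25e-05, the smallest it can give, and an adjusted p of 8.75e-05 over 7 contrasts. All 12 lot-matched pairs were lower without G9a, and the 12 G9a-deficient libraries (0.0166 to 0.349) did not overlap the 12 G9a-intact ones (0.394 to 1.86). The log2 difference was −3.06 in lot 1, −2.35 in lot 4 and −3.43 in lot 7. It was −2.42 between SG and 33-6 and −3.47 between 3S1G and SE, with an exact permutation p of 0.005 each.

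**Figure D1:**
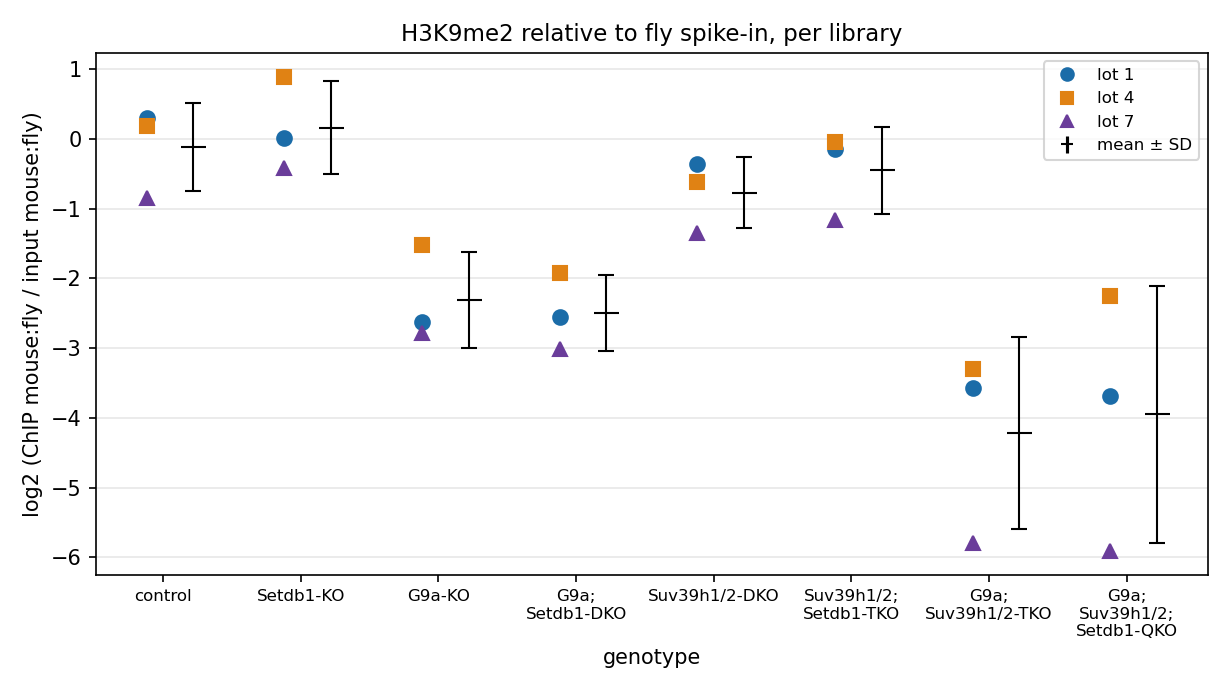
Log2 of the normalised H3K9me2 ratio (vertical axis, no unit) for each of the 8 genotypes (horizontal axis). Each symbol is 1 library, marked by lot, and the bar beside it is the mean ± SD of 3 libraries. The 12 G9a-deficient libraries lie between −5.91 and −1.52, all below the 12 G9a-intact libraries, and lot 7 is the lowest in each genotype.

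The next comparison asked whether Suv39h1/2, best known for trimethylating H3K9 in pericentromeric heterochromatin, also contribute to total H3K9me2. H3K9me2 was lower in the Suv39h1/2-deficient lines, by less than in the G9a-deficient lines. Over 4 pairs of genotypes the fall was 2.23-fold, a log2 difference of −1.16 with a 95% interval of −2.00 to −0.32. Suv39h1/2-DKO cells stood at 63.5% of the control level by geometric mean, and G9a;Suv39h1/2-TKO cells stood at 5.81%, against 21.9% in G9a-KO cells. The exact two-sided permutation test gave p = 0.00325 and an adjusted p of 0.0114 over 7 contrasts, and 12 of 12 lot-matched pairs were lower. The log2 difference was −0.72 in lot 1, −0.96 in lot 4 and −1.79 in lot 7. With lot as a term the interval was −1.66 to −0.66. With lot as a replicate block the adjusted p was 0.00171 by an exact sign-flip permutation test. It was 0.000665 by a permutation test of residuals within lots. The call was lost when lot 1 was left out (−1.38, adjusted p = 0.119, exact permutation test), on the linear scale and with medians (−0.76). Without the 2 lot 7 libraries of 3S1G the difference was −0.72, with an adjusted p of 0.0489 by the exact permutation test. SE and 3S1G are also the lines whose processing notes name a read-trimming step, so this contrast follows that step as well.

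Whether Setdb1, which trimethylates H3K9 at retroelements, is needed for total H3K9me2 was tested within each line by comparing 4OHT-treated with untreated cells. No change in H3K9me2 was detected. The normalised ratio was 1.20 ± 0.581 (SD, n = 3) in Setdb1-KO cells, against 0.979 ± 0.368 (SD, n = 3) in control cells. In the G9a-deficient background it was 0.186 ± 0.0714 (SD, n = 3) after 4OHT and 0.219 ± 0.113 (SD, n = 3) before. The corresponding values in the Suv39h1/2-deficient line were 0.774 ± 0.286 and 0.610 ± 0.198 (SD, n = 3 each), and in 3S1G they were 0.102 ± 0.0991 and 0.0681 ± 0.0443 (SD, n = 3 each). Averaged over the 4 lines the log2 difference was 0.17, with a 95% interval of −0.67 to 1.01 and an exact permutation p of 0.634 (adjusted p = 0.798). Of 12 lot-matched pairs, 5 were lower and 7 higher after 4OHT. By line, 0 of 3 were lower in SE (log2 differences of 0.18 to 0.57), 1 of 3 in 33-6 and 2 of 3 each in SG and 3S1G. The log2 difference was −0.03 in lot 1, 0.48 in lot 4 and 0.07 in lot 7, and it was 0.05 in 33-6 and SG and 0.30 in SE and 3S1G. With lot as a term the interval narrowed to −0.33 to 0.67, so changes within those limits are not excluded. Every 4OHT-treated sample is labelled as lacking Setdb1, so loss of Setdb1 cannot be separated from the 4OHT treatment itself. Deletion of Setdb1 was not checked, because the values hold no gene-level signal.

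The design also asks whether loss of one enzyme matters more when another is absent. None of the 4 interactions in H3K9me2 passed the threshold. Suv39h1/2-DKO cells had 63.5% of the H3K9me2 of control cells, and G9a;Suv39h1/2-TKO cells had 26.6% of that of G9a-KO cells. The latter is a log2 difference of −1.91, which ran from −3.02 to −0.94 over the lots and was −0.94 with medians. After 4OHT, Suv39h1/2;Setdb1-TKO cells had 65.4% of the H3K9me2 of Setdb1-KO cells, and QKO cells had 36.5% of that of G9a;Setdb1-DKO cells. The G9a-by-Suv39h1/2 interaction averages the untreated and the 4OHT-treated pairs. It was −1.05 on the log2 scale, with a 95% interval of −2.73 to 0.63 and a permutation p of 0.210 (adjusted p = 0.489). With lot as a term the interval was −2.05 to −0.05, which leaves out 0, and the adjusted permutation p was 0.0900 with residuals permuted within lots. On the linear scale the interaction was positive, but that scale compares absolute falls of the ratio and not folds. In untreated cells, Suv39h1/2 loss took the ratio from 0.979 to 0.610 with G9a and from 0.219 to 0.0681 without it. The log2 interaction shrank to −0.16 without the 2 lot 7 libraries of 3S1G, the lowest of the series. The other interactions were −0.25 for Setdb1 with G9a, 0.25 for Setdb1 with Suv39h1/2 and 0.41 for all 3, with adjusted permutation p-values of 0.798 each.

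Against the control alone, the geometric mean H3K9me2 was 121% in Setdb1-KO, 79.2% in Suv39h1/2;Setdb1-TKO, 63.5% in Suv39h1/2-DKO, 21.9% in G9a-KO, 19.2% in G9a;Setdb1-DKO, 7.01% in the QKO and 5.81% in G9a;Suv39h1/2-TKO. Genotypes close to each other in this list are not ranked. Without lot 4 the log2 difference of the QKO went from −3.83 to −4.53, below the −4.42 of G9a;Suv39h1/2-TKO, and without lot 7 it was −3.22. That of G9a-KO went from −2.19 to −2.82 with medians. That of Setdb1-KO went from 0.28 to −0.18 with medians and −0.20 without input correction. The 4 G9a-deficient genotypes were below the control in all 3 lots, and their ranges did not overlap it. Their log2 differences from the control ran from −2.19 for G9a-KO (95% interval −3.88 to −0.51) to −4.11 for G9a;Suv39h1/2-TKO (95% interval −5.79 to −2.42). The 3 G9a-intact genotypes overlapped the control, and their intervals, which take no account of lot, included 0. Within lots, Suv39h1/2-DKO was also below the control in 3 of 3 (−0.81 to −0.50), Suv39h1/2;Setdb1-TKO in 3 of 3 (−0.45 to −0.23) and Setdb1-KO in 1 of 3. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, which was the value of each G9a-deficient genotype (adjusted p = 0.175 over 7 genotypes).

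Lamin B1 was profiled in the same genotypes, which sets chromatin at the nuclear lamina beside H3K9 methylation. Lamin B1 signal was moderately lower in the G9a-deficient genotypes. It was 0.879 ± 0.0466 (SD, n = 2) in control cells and 0.659 ± 0.126 (SD, n = 2) in G9a-KO cells, and 1.06 ± 0.406 (SD, n = 2) in Suv39h1/2-DKO cells and 0.688 ± 0.0997 (SD, n = 2) in G9a;Suv39h1/2-TKO cells. Over the 4 pairs of genotypes the fall was 1.39-fold, a log2 difference of −0.48 with a 95% interval of −0.83 to −0.13. The exact two-sided permutation test gave p = 0.00154, the smallest it can give, and an adjusted p of 0.0108 over 7 contrasts. All 8 lot-matched pairs were lower, and the 8 G9a-deficient libraries (0.506 to 0.758) did not overlap the 8 intact ones (0.769 to 1.34). Without input correction they did overlap, with log2 mouse to fly ratios of 2.50 to 2.94 and 2.82 to 3.83. The log2 difference was −0.66 in lot 1 and −0.30 in lot 4, and −0.48 both between SG and 33-6 and between 3S1G and SE (exact permutation p = 0.0556 each, the smallest possible in these subsets). With lot as a replicate block the adjusted p was 0.0547 by an exact sign-flip permutation test, whose smallest p of 0.00781 this difference reached, and 0.139 with residuals permuted within lots, a permutation test without that limit. The call was also lost on leaving out any 1 of 6 libraries: control lot 1, Setdb1-KO lot 4, G9a;Setdb1-DKO lot 4, Suv39h1/2;Setdb1-TKO lot 1 or either lot of G9a;Suv39h1/2-TKO, with log2 differences of −0.51 to −0.41.

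**Figure D2:**
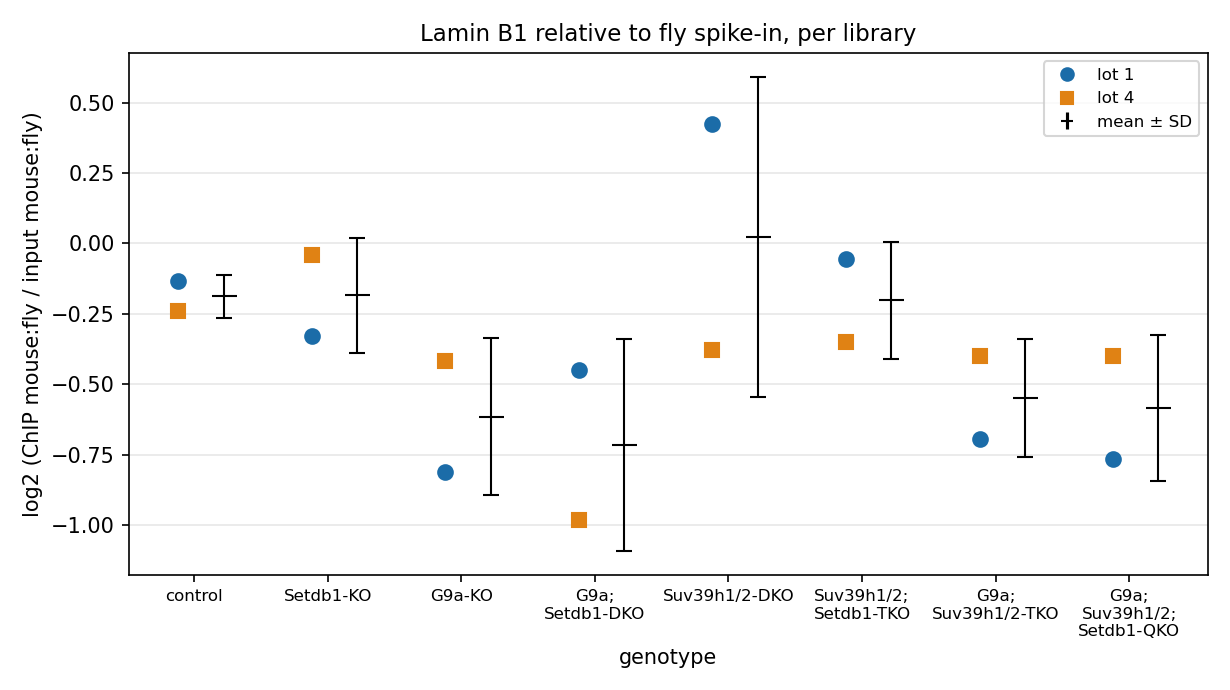
Log2 of the normalised Lamin B1 ratio (vertical axis, no unit) for each of the 8 genotypes (horizontal axis). Each symbol is 1 library, marked by lot, and the bar beside it is the mean ± SD of 2 libraries. The 8 G9a-deficient libraries lie between −0.98 and −0.40 and the 8 intact ones between −0.38 and 0.43.

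Neither loss of Setdb1 nor loss of Suv39h1/2 gave a detectable change in Lamin B1. After 4OHT the log2 difference was −0.09, with a 95% interval of −0.44 to 0.26 and an exact permutation p of 0.512 (adjusted p = 0.981). It was lower in 5 of 8 lot-matched pairs, −0.10 in lot 1 and −0.08 in lot 4, and −0.05 in 33-6 and SG and −0.13 in SE and 3S1G. For Suv39h1/2 the log2 difference was 0.10, with a 95% interval of −0.25 to 0.45 and an exact permutation p of 0.475 (adjusted p = 0.981). It was higher in 5 of 8 lot-matched pairs, 0.16 in lot 1 and 0.04 in lot 4. Lamin B1 stood at 98.9% of the control to 116% in the 3 other G9a-intact genotypes and at 69.3% to 77.9% in the 4 G9a-deficient ones, by geometric mean. This split depends on the input correction, without which the log2 difference from the control went from 0.0027 to −0.67 in Setdb1-KO and from −0.43 to −1.06 in G9a-KO. The 4 interactions lay between −0.08 and 0.29 on the log2 scale, with adjusted permutation p-values of 0.981 each. For single genotypes an exact permutation test of 2 against 2 libraries cannot go below p = 0.333. The 95% intervals of their differences from the control, from the pooled SD, all included 0, among them −1.13 to 0.28 for G9a-KO and −1.23 to 0.17 for G9a;Setdb1-DKO.

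The input libraries show how evenly the fly chromatin had been added. Fly reads made up 5.90% to 12.1% of the input reads, against 10% of the DNA mixed in, and the mouse to fly ratio ranged from 7.24 to 15.9. By genotype the mean ratio was highest in the control, at 14.1 ± 1.48 (SD, n = 3). In the other genotypes it ran from 10.4 in Setdb1-KO and 10.8 in G9a-KO to 12.1 in Suv39h1/2;Setdb1-TKO (n = 3 each). None of the 3 effects tested in this ratio passed the threshold, and interactions were not part of these tests. The log2 differences were −0.10 for Setdb1, −0.09 for G9a and 0.06 for Suv39h1/2, with exact permutation p-values of 0.441, 0.520 and 0.649 (adjusted p = 0.649 each over 3 contrasts). Of the 12 lot-matched pairs, 9 were lower after 4OHT, 8 were lower without G9a and 6 were lower without Suv39h1/2. Within lots 1, 4 and 7 these differences were −0.07, −0.19 and −0.04 for Setdb1, −0.15, −0.16 and 0.05 for G9a, and 0.07, 0.06 and 0.05 for Suv39h1/2. The ratio did differ between lots, from 14.2 ± 0.878 (SD, n = 8) in lot 7 to 10.3 ± 2.52 (SD, n = 8) in lot 4. The mean log2 deviation from the genotype means was 0.29 in lot 7, −0.08 in lot 1 and −0.21 in lot 4, with an exact permutation p of 0.00100 over the orders of the lots.

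**Figure D3:**
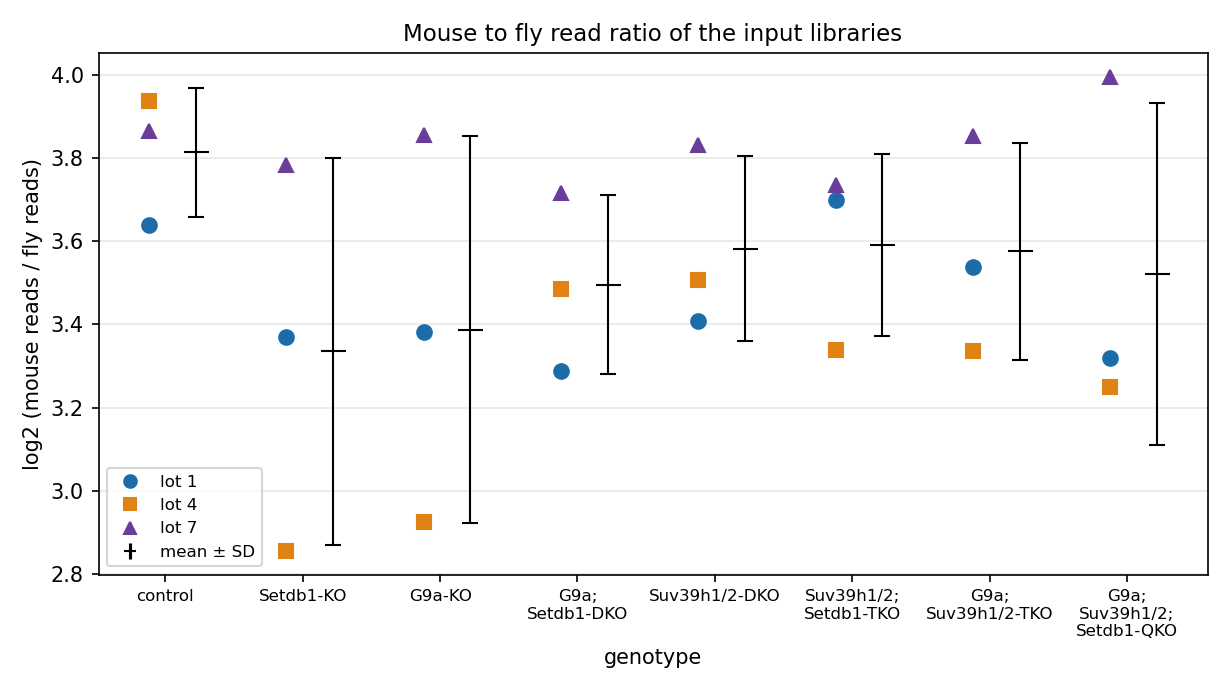
Log2 of the mouse to fly read ratio (vertical axis, no unit) of the 24 input libraries by genotype (horizontal axis). Each symbol is 1 library, marked by lot, and the bar beside it is the mean ± SD of 3 libraries. Lot 7 is the highest in 7 of 8 genotypes.

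Whether H3K9me2 and Lamin B1 vary together was examined over genotype and lot, where the 16 pairs of libraries fall into separate G9a-intact and G9a-deficient clusters on H3K9me2. No relation was detected within either cluster. Among the 8 G9a-intact pairs Pearson's r was 0.0179 (exact permutation p = 0.961, adjusted p = 0.961) and Spearman's rho was 0.262 (exact permutation p = 0.536, adjusted p = 0.882). Among the 8 G9a-deficient pairs r was 0.116 (exact permutation p = 0.784, adjusted p = 0.961) and rho was 0.0714 (exact permutation p = 0.882, adjusted p = 0.882). Adjustment was over the 2 clusters. Without the 2 pairs farthest from the median H3K9me2, r was −0.650 (exact permutation p = 0.167) and −0.312 (exact permutation p = 0.524). The plan had been to correlate all 16 pairs, the genotype means, and the pairs within each lot and each set of lines. The split by G9a status was not planned and replaced these because of the clusters. No pooled r is therefore given, and 4 pairs per lot or per set of lines within a cluster are too few for a value. Both measures share their input library, and without input correction r was 0.175 in the intact cluster and −0.413 in the deficient one.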

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

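Permuting residuals within lots and leaving out the 2 lot 7 libraries of 3S1G were chosen after seeing the data. Of 694 alternative values, 13 lost a call, and 63 changed sign, all in results that passed no test. Most of the 694 belong to results with no call to lose, and some repeat the main measure. The lost calls were 10 for Lamin B1 without G9a and 3 for H3K9me2 without Suv39h1/2. H3K9me2 was lower without G9a past the threshold under every alternative run, from −3.47 to −2.42 on the log2 scale. The lower H3K9me2 without Suv39h1/2 kept its sign (−1.38 to −0.84 over each single lot or library left out, and −0.72 without the 2 lot 7 libraries of 3S1G) and lost its call on the linear scale (−0.26, adjusted p = 0.0698), with medians (−0.76, adjusted p = 0.0574) and without lot 1 (−1.38, adjusted p = 0.119), all by permutation tests. Without lot 1 the difference was larger and rested on fewer libraries. For the other losses the cause was not tested.

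The lower Lamin B1 without G9a lay between −0.66 and −0.30 over lots and libraries left out. By permutation tests, its value of −0.48 lost the call with lot as a replicate block (adjusted p = 0.0547) and with residuals permuted within lots (adjusted p = 0.139). It lost it in 33-6 and SG alone (−0.48) and SE and 3S1G alone (−0.48), where the exact permutation test has too few assignments. The block changed no other call. For the G9a-by-Suv39h1/2 interaction in H3K9me2 (−1.05) the block gave an adjusted permutation p of 0.128, and residuals permuted within lots gave 0.0900, in a range of 0.0900 to 0.823 over all alternatives.

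Over lots and libraries left out, H3K9me2 ranged from −0.0412 to 0.42 for Setdb1, −0.68 to 0.24 for Setdb1 with G9a, −0.17 to 0.74 for Setdb1 with Suv39h1/2 and −0.44 to 1.40 for all 3. Lamin B1 ranged from −0.19 to 0.0103 for Setdb1, −0.0023 to 0.20 for Suv39h1/2, −0.40 to 0.48 for Setdb1 with G9a, −0.36 to 0.20 for Setdb1 with Suv39h1/2, −0.52 to 0.52 for G9a with Suv39h1/2, −0.15 to 0.73 for all 3, and −0.14 to 0.56 for Suv39h1/2-DKO against the control. Without input correction, H3K9me2 was 0.0072 for Setdb1 with G9a and −0.23 for all 3, and Lamin B1 was 0.0945 for Setdb1 with Suv39h1/2 and −0.83 for all 3. It also moved Lamin B1 against the control, to −0.67 in Setdb1-KO, −1.06 in G9a-KO, −0.93 in G9a;Setdb1-DKO, −0.12 in Suv39h1/2-DKO, −0.71 in G9a;Suv39h1/2-TKO and −0.90 in the QKO, and r in the G9a-deficient cluster to −0.413. An averaged input gave Lamin B1 values of −0.0379 for G9a with Suv39h1/2 and −0.18 for all 3. The linear scale gave 0.28 for G9a with Suv39h1/2 in H3K9me2 and −0.0418 in Lamin B1, in units of the ratio and not of log2. Medians gave −0.85 for all 3 in H3K9me2. Values without input correction or with an averaged input move through the input ratios alone, by definition. For Setdb1-KO and the control these ratios were 10.3 and 12.5 in lot 1, and 7.24 and 15.3 in lot 4. Why the inputs differed, and the cause of the other moves, was not tested. The deposited scaling factor is the main measure itself and moves nothing, medians and means of 2 Lamin B1 lots are equal, and a correlation without a lot leaves 4 pairs, so no value is given. Counting error is at most 0.219% of any ratio if each read pair is independent, which is too small to limit these results. Whether duplicates were removed is not given, so the number of distinct molecules is unknown.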

Other observations

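The tests below of input ratio, Lamin B1 yield, lot and counting error were chosen after the results had been seen, and that of proportionality to H3K9me2 before its result was seen. The share of fly reads in the H3K9me2 libraries, not corrected for input, rises as the mouse signal falls. The series holds no mock precipitation, so background mouse reads in these libraries were not measured. Fly reads made up 7.49% ± 3.02 (SD, n = 3) of the H3K9me2 ChIP reads in control cells and 32.3% ± 4.93 (SD, n = 3) in G9a-KO cells. They made up 59.7% ± 17.1 (SD, n = 3) in G9a;Suv39h1/2-TKO and 56.2% ± 22.9 (SD, n = 3) in QKO cells, with single libraries from 49.3% to 79.4% and from 33.3% to 79.1%. The highest shares of both were in lot 7, where H3K9me2 was 3.21% and 2.98% of the lot 7 control. The 16 Lamin B1 libraries held 6.55% to 15.0% fly reads.

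H3K9me2 was lower in SE and 3S1G, the lines with Suv39h1/2 loss and with the trimming step. The inputs differed by 0.0593 on the log2 scale (95% interval −0.22 to 0.34), which does not test trimming, since a shift shared by ChIP and input is divided out. A lower ChIP yield shared by mouse and fly chromatin would cancel in the ratio, so Lamin B1 does not test it. A lower yield of the mouse chromatin alone, whatever the antibody, would lower Lamin B1. Lamin B1 differed by 0.10 (95% interval −0.25 to 0.45) in lots 1 and 4, its only lots. H3K9me2 differed by −0.84 in those lots and by −1.16 over all lots, and the Lamin B1 interval leaves out both values. Trimming or another difference between the sets that acts on H3K9me2 libraries alone stays open, as does clonal difference between lines, since each genotype is 1 line. Loss of Suv39h1/2 itself remains a hypothesis that this design cannot separate from the set of lines.

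H3K9me2 was lowest in lot 7 in all 8 genotypes, with a mean log2 deviation of −0.89 from the genotype mean, which its higher input ratio explains in part at most (−0.60 without input correction, exact permutation p = 0.00164 over lot orders) and counting error, at most 0.199%, does not explain. The 2 genotypes of 3S1G deviated by −1.77 and the other 6 by −0.60, a difference of −1.18 (95% interval −2.13 to −0.22, from the spread of lots 1 and 4 and widened for picking 1 of 4 lines). Part of it comes from the high lot 4 library of the quadruple knockout, at 1.70 above its genotype mean against at most 0.92 elsewhere, although lot 7 minus lot 1 was also lowest in 3S1G (−2.24 and −2.23, against −1.15 to −0.15). A factor shared by the whole lot stays open, since the spread over all 8 genotypes in lot 7 was 1.59 times that expected from lots 1 and 4, with a 95% interval of 0.712 to 3.56 that includes 1. These were the last of several tests tried: permuting genotypes had a fixed outcome once 3S1G was picked, permuting lots within genotypes (permutation p = 0.0191) made calls in 15.0% of simulations with no effect, and no biological explanation was tested.

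Lamin B1 was lower in the G9a-deficient lines. The input ratio of these lines does not account for it, since without input correction the difference was −0.63 (adjusted p = 0.0216, exact permutation test). If Lamin B1 followed log2 H3K9me2 in proportion, loss of Suv39h1/2 would change it by −0.15, from H3K9me2 differences of −2.71 for G9a and −0.84 for Suv39h1/2 in lots 1 and 4. The observed 0.10 has a 95% interval of −0.25 to 0.45 that holds both −0.15 and 0, so these data cannot decide between proportional loss and none. Loss of G9a is a candidate explanation, and differences between single lines remain open.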
